A study of Malus hupehensis and Malus pumila and Malus sylvestris with 10 samples.

How the data were processed

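RNA sequencing of phloem was carried out in 5 kinds of apple rootstock, with 2 samples of each, collected 60 days after bud break per the sample titles and the design text. The description labels of the 8 samples other than Malus sylvestris carry a day number that counts up by 1 from sample to sample, starting at 60; the titles were followed. Values were at hand for 1 of the 5, the crab apple Malus sylvestris, which the labels class as vigorous. The other 8 samples, of the dwarfing rootstocks A1d, B9 and M9 and of the vigorous PYTC, were not analysed here. The contrasts that the design calls for, dwarfing against vigorous and the gibberellin-insensitive mutant A1d against its wild type PYTC, were therefore not made. The labels number the samples 1 and 2 and do not say whether these came from separate trees, so the spread between them may be technical.

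Per the labels, total RNA was extracted with a kit for small and large RNA and made into libraries with a stranded kit that selects polyadenylated RNA. Trimmomatic, HISAT2, Cufflinks and HTSeq are named in the submitters' processing notes, without version, order or role. The genome build, the annotation and the tool that made the values are not given in the sources used here. The deposited values are FPKM, per the labels and the file's name: fragments relative to gene length and to sequencing depth, which the authors scaled by each library's own total. FPKM divides by gene length and by library total, so a library in which a few genes take more of the fragments shows lower values for the other genes. How reads shared by near-identical gene copies, which are common in the duplicated apple genome, were assigned is not given in the sources used here, so values of such genes are uncertain.

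The table holds 38700 gene IDs and 2 columns of values. Both columns were matched to their samples by species and replicate number. The IDs were not paired with gene names in the sources used here, and no annotation was used. For this reason the 22 gene lists fixed in advance (sieve elements, sugar transport, hormones, cell walls, other cell types and others) could not be applied, and genes are given by ID. The rule for IDs, also fixed in advance, allows at most 2 in each direction where names are missing. They are the 2 IDs most above and the 2 most below in library 2 against library 1, in log2(FPKM + 1), among IDs with a mean of 10 FPKM or more. The 2 IDs with the highest mean are given as well.

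Levels were averaged over both libraries and are given as mean ± SD with n = 2. An ID was counted as detected at 1 FPKM or more in both libraries. Differences between the libraries were taken as library 2 minus library 1 on the log2(FPKM + 1) scale, with a pseudocount of 1. This understates the change of low genes. Differences of over 2-fold were counted among IDs with a mean of 1 FPKM or more. No group comparison was possible, so no p-value between conditions was computed.

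The table gives no fragment counts. Ratios between the columns for low genes fell on fractions of small whole numbers. Of these genes, 835 shared 1 ratio, 0.894, equal to about the precision of the listed values. It is the ratio of library 2 to library 1 in depth. The library totals were then found as the largest at which gene lengths came out whole, within 0.003 of a base, for at least 65% of genes with irreducible ratios. The smallest length from 50 to 30000 bases that made both values whole fragments was taken for each gene. All 35889 genes above 0 in either library, 100% of them, came out whole. The recovered fragments summed to 90.2% of the inferred total in each library. A sum of 90.0% is predicted if the total is the sum over the listed genes and fragments and length sometimes share a factor, which the smallest length cannot show. Recovered fragments are thus the fewest that fit. They were used only for depth and for counting error, and intervals of ratios and floors cover counting error only. Intervals of shares of genes treat genes as independent.

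The recovery was tested on simulated data for the 2 M. sylvestris libraries over 38700 genes. Both totals were recovered exactly, and 83.8% of genes with fragments in both libraries had their exact fragments. Each gene with 10 or more fragments was tested against the ratio of the totals with a two-sided exact binomial test and Benjamini-Hochberg adjustment. In the simulation this test called 83% of 100 genes changed 2-fold, 99% of 100 genes changed 4-fold, and 2 unchanged genes. The last made up 0.0069% of the unchanged genes tested, with 29334 genes tested in all. The changed genes were drawn only from those with 100 or more recovered fragments over both libraries. The simulated totals also differed from those inferred, with library 2 the deeper. The shares called therefore do not hold for all tested genes or for these depths. The test compares 2 libraries of 1 group, not conditions. Sampling noise alone was simulated with 100 pairs of libraries drawn from the pooled fragment rates (Poisson).

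Alternatives fixed before the data were examined were other FPKM floors (0.5, 5 and any value above 0), pseudocounts of 0.1 and 0.01, other filters on low values, rescaling by the median ratio, 100 in place of 10 genes, and each library alone. The binomial test, floors in recovered fragments and the rank correlation for IDs with a mean of 1 FPKM or more were added after the data were seen. The rank correlation over all IDs was planned beside Pearson's r. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.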

Results

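The series set out to compare phloem of dwarfing and vigorous apple rootstocks in active growth, 60 days after bud break. Rootstocks carry the grafted scion, and dwarfing ones reduce the size of the tree. Phloem is the tissue that carries sugars and signals from the leaves. The labels describe 5 rootstocks with 2 samples each: A1d, a mutant of Malus hupehensis with reduced sensitivity to gibberellin, the growth hormone; its wild type PYTC; the dwarfing clones B9 and M9; and the crab apple Malus sylvestris as a vigorous control. Expression values of the 2 M. sylvestris samples are described here. No contrast with another rootstock was made.

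The table gave FPKM values for 38700 gene IDs. Library 1 summed to 660235 FPKM and library 2 to 666186. From the steps between low values, library 1 was inferred to rest on 18538960 fragments and library 2 on 16572066. A gene of the median length, 1258 bases, with no fragment could therefore have had up to 0.129 FPKM in library 1 and 0.144 FPKM in library 2, at the limit of 3 fragments that a count of 0 allows.

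The share of listed genes detected in the phloem of M. sylvestris depended on the floor. Of the 38700 IDs, 26292 (67.9%) reached 1 FPKM in both libraries, with 27393 in library 1 and 26883 in library 2 (27138 ± 361, SD, n = 2). At a floor of 5 FPKM, 17922 IDs (46.3%) passed in both libraries. The group at 10 FPKM or more held 12713 ± 93.3 IDs (SD, n = 2), and the group at 100 FPKM or more held 938.5 ± 21.9 (SD, n = 2). Levels of 1000 FPKM or more were reached by 34.5 ± 2.12 IDs (SD, n = 2), 31 of them in both libraries. A further 2811 IDs (7.26%) were listed at 0 in both libraries. The median ID stood at 4.66 FPKM in library 1 and 4.45 FPKM in library 2.

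The transcript pool was spread over many genes rather than held by a few. The 10 IDs with the highest mean took 6.39% ± 0.0807 of the summed FPKM (SD, n = 2), the 100 highest took 18.0% ± 0.604 and the 1000 highest took 42.6% ± 0.805. MD15G1253900 was the most abundant transcript, at 14857 ± 706 FPKM (SD, n = 2). It alone took 2.17% of the sum in library 1 and 2.31% in library 2. MD05G1028100 followed at 6776 ± 659 FPKM (SD, n = 2), with 7243 FPKM in library 1 and 6310 FPKM in library 2. What these genes encode is not given in the sources used here.

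The question open within this group is how far its samples agree. That spread would be the error for differences from another rootstock only if the samples came from separate trees, which the labels do not say. It is taken across genes here, from 1 pair of libraries, and is not the error of a single gene. Across genes, which are not independent replicates, log2(FPKM + 1) of the libraries correlated with Pearson's r = 0.989 and Spearman's rho = 0.985. Among the 27203 IDs with a mean of 1 FPKM or more, the difference between the libraries had a median of -0.02 and an SD of 0.30 on the log2 scale. The SD was 0.43 for the 2947 IDs between 1 and 2 FPKM, and 0.22 for the 939 IDs at 100 FPKM or more. Sampling noise alone, simulated from the recovered fragments, gave an SD of 0.29 in the first of these level groups and 0.04 in the last.

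**Figure D1:**
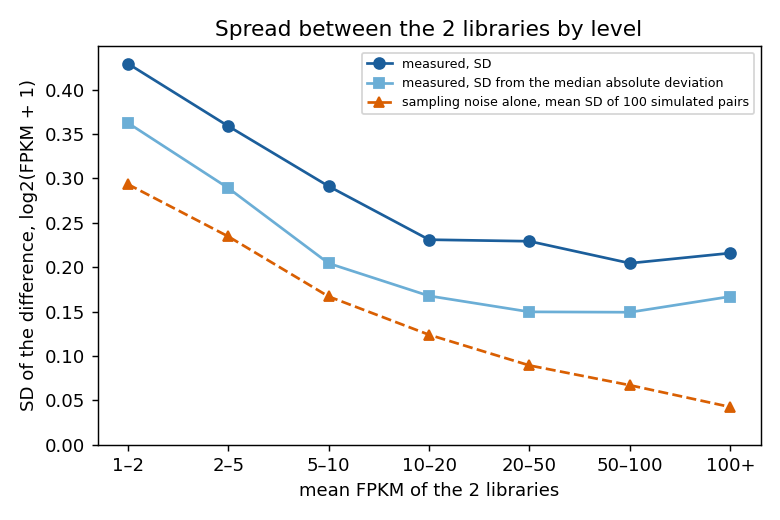
Standard deviation of the difference between the libraries (log2(FPKM + 1), vertical axis) for genes grouped by mean FPKM (horizontal axis), as measured, as estimated from the median absolute deviation, and with sampling noise alone in 100 simulated pairs. The measured SD falls from 0.43 to 0.22 from the lowest to the highest group and lies above the simulated SD in each of the 7 groups.

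The 2 columns were thus not 1 set of values deposited in duplicate. Spread beyond sampling noise does not by itself show whether the samples were prepared as separate libraries. Of 30618 IDs with 10 or more recovered fragments, 4696 (15.3%) differed beyond sampling noise at an adjusted p under 0.05 in the exact binomial test, 1935 higher and 2761 lower in library 2. In 2957 of these calls (63.0%) the libraries differed by less than 1.5-fold. The median chi-square statistic per gene was 1.27, against 0.455 with sampling noise alone.

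Most differences of over 2-fold lay in 1 direction. They were found at 334 of the 27203 IDs (1.23%), of which 58 were higher and 276 lower in library 2. The lower genes made up 82.6% of them (95% exact interval 78.1% to 86.5%). This interval treats genes as independent draws, which they are not, and rests on 1 pair of libraries. The exact binomial test called 286 of the 334, namely 42 of the higher and 244 of the lower IDs. Rescaling the libraries by their median ratio, a shift of 0.02 on the log2 scale, left 59 higher and 255 lower. The count depended on the pseudocount: it was 884 (181 higher and 703 lower) with a pseudocount of 0.1 and 991 (209 higher and 782 lower) with 0.01. Among the 12757 IDs with a mean of 10 FPKM or more, 54 were over 2-fold apart.

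The 2 strongest single-gene differences in each direction in that better-covered group were far outside its spread, whose SD was 0.23 on the log2 scale. MD04G1139100 stood at 68.6 FPKM in library 1 and 1.23 FPKM in library 2, on 375 and 6 fragments, a difference of -4.97 on the log2(FPKM + 1) scale. The ratio of library 1 to library 2 was 55.9 (95% exact interval 25.4 to 153). MD16G1011000 stood at 27.1 and 1.29 FPKM, a ratio of 21.1 (12.4 to 39.0). MD15G1346300 was higher in library 2, with 5.75 FPKM in library 1 and 86.4 FPKM in library 2, on 21 and 282 fragments, a difference of 3.69 on the same scale and a ratio of library 2 to library 1 of 15.02 (9.64 to 24.7). MD11G1295000 stood at 6.96 and 51.5 FPKM, a ratio of 7.40 (5.69 to 9.76). All 4 passed the exact binomial test, with adjusted p-values from 4.88e-91 for MD04G1139100 to 1.45e-63 for MD15G1346300. These p-values compare 2 libraries of 1 rootstock, and with 1 library on each side no difference has a replicate check. A mean over the 2 samples describes neither for these genes: MD04G1139100 averaged 34.9 ± 47.6 FPKM (SD, n = 2).

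**Figure D2:**
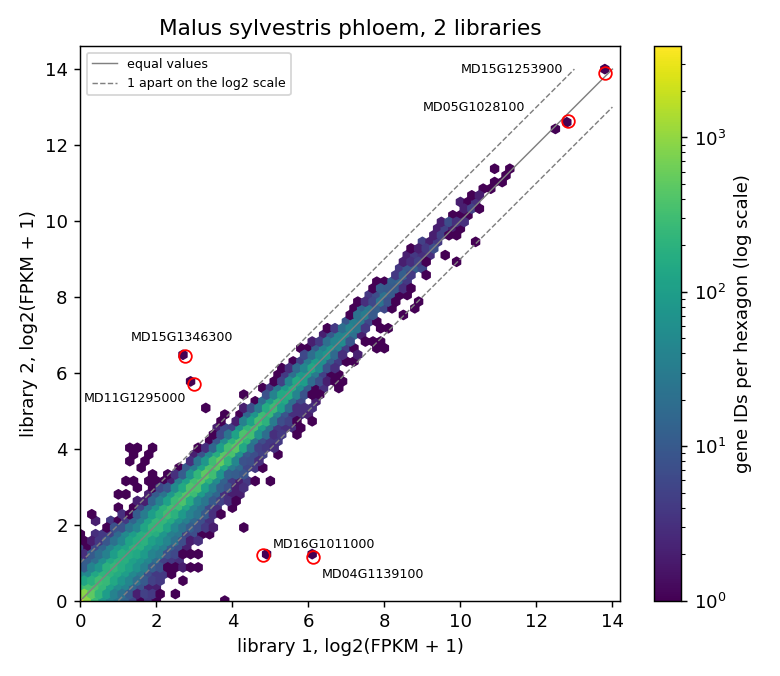
Expression of all 38700 gene IDs in library 1 (horizontal axis) and library 2 (vertical axis) of M. sylvestris phloem, as log2(FPKM + 1), with colour for the number of IDs per hexagon on a log scale, the solid line for equal values and dashed lines 1 apart. Circles mark the 2 most abundant IDs, near the line of equal values. They also mark the 2 IDs most above and the 2 most below in library 2, among those with a mean of 10 FPKM or more.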

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

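The number of detected genes kept within 1.5 times of 26292 under each alternative run, from 17922 at a floor of 5 FPKM to 33366 at any value above 0. With 1 library alone it was 26883 or 27393, and 27991 IDs had 10 or more recovered fragments in both libraries, a setting chosen after the data were seen. Pearson's r fell from 0.989 to 0.979 with a pseudocount of 0.1, to 0.953 with 0.01 and to 0.982 for IDs with a mean of 1 FPKM or more. The rank correlation was 0.980 for those IDs. The number of genes over 2-fold apart depended most on the processing. It rose from 334 to 884 with a pseudocount of 0.1 and to 991 with 0.01, since a smaller pseudocount damps low genes less. At a filter of 10 FPKM it fell to 54. That filter keeps 12757 of the 27203 IDs, and their spread is smaller (SD 0.23 against 0.30 on the log2 scale). The count was 401 with no filter, 314 after rescaling and 287 with 20 or more recovered fragments. Lower genes outnumbered higher ones in library 2 under all of these, from 78.9% with a pseudocount of 0.01 to 90.7% at the filter of 10 FPKM. The exact binomial test, added after the data were seen, asks for a difference beyond sampling noise and not of a given size. It called 4696, with 1935 higher and 2761 lower, so lower genes made up a smaller share, 58.8%. The share of the 10 highest genes was 6.33% or 6.45% with 1 library alone, and that of the 100 highest was 18.0%. Depth limits the low genes: between 1 and 2 FPKM the median gene had 31 fragments in library 1 and 24 in library 2. No paired analysis was possible because the table holds 1 group. The planned contrasts between rootstocks, the tests of gene lists and the exclusion of organelle and ribosomal RNA genes were not run, for want of the other groups' values and of gene names.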

Other observations

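Apart from rescaling by the median ratio, an alternative fixed before the data were examined, the tests in this part were chosen after the patterns were seen, and that of sampling noise after its result was partly known. Genes with a longer recovered length stood at a higher median level. The median level rose from 2.36 ± 0.114 FPKM (SD, n = 2) in the shortest 20% of genes, up to 622 bases, to 4.88, 6.17, 6.88 and then 7.22 ± 0.144 FPKM in the longest 20%, from 2155 bases. Lengths here are the smallest that give whole fragments. Genes at 0 in both libraries have none. Grouped by level instead, genes above 0 in both libraries had a median length of 1126 bases in the lowest 20%. It was 1481 bases in the 20% next to the highest and 1261 in the highest 20%, so the relation was not uniform. Whether the rise reflects the genes or the extent of their models was not tested.

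Genes also differed by the digits after MD in their ID. In common apple gene IDs these digits give the chromosome, with MD00 for sequence not placed on one, although the sources used here do not state this for the table. Of the 1324 IDs that begin with MD00, 60.0% reached 1 FPKM in both libraries, against 67.9% of all IDs, and their median was 2.62 ± 0.117 FPKM (SD, n = 2). Of the 3427 IDs that begin with MD15, 72.1% did, with a median of 5.61 ± 0.139 FPKM (SD, n = 2). In a two-sided permutation test of the prefix over IDs, both had p = 1e-05, the smallest that 100000 permutations can give, and an adjusted p of 9e-05 over 18 prefixes. MD16 was also above the rest (70.6%, adjusted permutation p = 0.049), and the other prefixes did not pass. IDs are not independent replicates. Levels of successive IDs with a mean of 1 FPKM or more had a rank correlation of 0.0896, above the highest of 1000 shuffles, 0.0218. The permutation ignores this, so its p-values may be too small, and the call of MD16 is insecure. MD15 held 8.86% of the IDs and 11.5% ± 0.176 of the summed FPKM (SD, n = 2), and 9.48% of the remaining sum without its most abundant gene.

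Between the libraries, 276 genes were over 2-fold lower in library 2 and 58 were higher. Of 100 pairs simulated with sampling noise alone, the median had 27.5 lower genes and the highest 42. Counting noise alone is thus argued against for these 2 libraries. The simulation sets the spread between 2 single samples against counting noise, so it does not tell other sources of the excess apart. A scaling shared by all genes is argued against as the whole cause, since the median ratio was a shift of only -0.02 on the log2 scale. Lower genes still made up 81.2% after rescaling by it, but so small a shift could move few genes across the limit. Scaling that differs with level is not covered by it. The share was 77.0% after the median of each level and length bin was subtracted. Median differences were small, from -0.0747 at 1 to 2 FPKM to 0.0429 at 100 FPKM or more. That subtraction could thus move few genes across the limit. It does not decide whether the skew of the largest differences changes with length or level. RNA from another tissue or a difference between trees or sampling may account for the excess and stays open. No biological explanation was tested, because the design names none within the group and the IDs carry no gene names.

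Neighbouring IDs moved together slightly. Across 27185 pairs of successive IDs with a mean of 1 FPKM or more, the difference between the libraries had a rank correlation of 0.052, above the highest of 1000 shuffles of the order within a prefix, 0.023. It was 0.019 for IDs 2 apart, near but under the highest shuffle, and -0.005 for IDs 5 apart. The shuffles were scored on successive IDs only, so whether the correlation ends before IDs 2 apart is not decided. The correlation was 0.0522 once the median of each level and length bin was subtracted. Median differences ran only from -0.0747 to 0.0429 across level groups, against an SD of 0.30. The subtraction could thus change the correlation little, and it shows only that the trend in medians is small. Strongly differing genes were argued against as the whole cause of the correlation. Without the 334 genes over 2-fold apart the correlation was 0.0477, above the highest shuffle of the genes kept, 0.022. Shared regulation of adjacent genes, copies of 1 gene that share reads and overlapping genes may each give such a pattern and were not told apart without sequences. The effect is small, at about 0.0347 for IDs with a mean of 10 FPKM or more.

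Among 33366 genes above 0 in both libraries, 39.7% had a recovered length that was a multiple of 3 (95% exact interval 39.1% to 40.2%), against 33.3% by chance, or 30.9% where many fragments let the smallest length lose a factor. The share was 52.5% (51.3% to 53.7%) in the 20% of genes with the lowest level, 33.6% in the 20% next to the highest and 36.0% (34.9% to 37.2%) in the 20% with the highest. A hypothesis that fits is that gene models made of coding sequence alone, without untranslated ends, are more frequent among weakly expressed genes. FPKM of such models may not be comparable with that of models that include untranslated ends, since the length in the denominator differs.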
